A study of Escherichia coli str. K-12 substr. MG1655 with 8 samples.

How the data were processed

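Total RNA from 8 cultures of Escherichia coli K-12 MG1655 was measured on 1-colour oligonucleotide arrays, 1 array per culture. Per the labels' protocols, RNA was reverse transcribed, amplified and labelled with the dye Cy3, and contaminating DNA had been digested before labelling. The labels put 4 cultures in the control group and 4 in the group exposed to TiO2 nanoparticles, and call the 4 of each group biological replicates. Per the file headers, the 8 arrays lay on 2 slides, with replicates 1 and 2 of both groups on slide 1 and replicates 3 and 4 of both groups on slide 2. Control arrays lay at positions 8 and 3 of each slide and TiO2 arrays at positions 6 and 1, so position on the slide cannot be told apart from group.

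The authors deposited the scanner output of each array, which holds linear spot intensity at 532 nm and local background, read with GenePix Pro 7.2.28.003 at a photomultiplier gain of 800 per the file headers. These scanner intensities were not normalized. The submitters' processing notes name R 2.11.1 and limma, without saying what each was used for. The authors' deposited value table holds 1 linear intensity per array for 4383 probes. Its normalization is not given in the sources used here. On control replicate 1 its values had a Spearman correlation of 0.9997 with the median spot intensity and 0.906 with the background-subtracted intensity. Its column medians ran from 209 to 240, and 99.997% of its values were whole multiples of 1/32, to a tolerance of 1e-9. Its scale is thus linear and it follows the spot intensities in direction, while its centring and normalization stay unknown. It was used only as an alternative, after taking log2.

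The design fixed before the data were examined had assumed processed-signal and detection columns of another scanner program, which these files lack. Its main scaling subtracted the 75th percentile of each array. Quantile normalization took its place after the files had been seen, which the missing columns did not require. The setting used instead was limma's normexp background correction with an offset of 50 on the median spot intensity and the median local background, log2, and quantile normalization between arrays over the 11494 non-control spots. The 3791 negative control spots of each array set its background level. A spot was called above background where its median intensity exceeded the 99th percentile of those control spots on the same array. Spots of 1 probe were averaged, a probe was kept where it was above background on at least 4 of the 8 arrays, and kept probes of a gene were averaged on the log2 scale. Spots with 50% or more saturated pixels were kept and counted.

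The array carries probes for several E. coli strains. A probe was taken as a K-12 probe where its locus tag (b number) matched the RefSeq gene table of assembly ASM584v2, which served for names and for which genes neighbour each other. In all 4073 probes matched, for 4052 genes, of which 20 had more than 1 probe. A further 161 probes had a b number that did not match, 52 carried only another kind of K-12 number, and 6405 belonged to other strains. The array's own gene name differed from the current symbol for 448 genes, and the current symbol is given. No build is named in the files, so no coordinates are given. Of the 4052 genes, 2280 passed the background criterion and were tested, and 1772 were too dim. Probes of 1 gene went in opposite directions for 2 tested genes, and 7 tested genes were saturated on at least 1 array.

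TiO2 arrays were compared with control arrays by limma (version 3.58.1, R 4.3.3), with lmFit and eBayes on the gene values, a two-sided moderated test and Benjamini-Hochberg adjustment over all tested genes. A gene was called at an adjusted p under 0.05. Fold values are 2 to the power of the log2 difference. Where a gene was not above background on any array of a group, or was saturated on every array of the brighter group, the fold is a bound, computed from the mean of the bright group against, per dim array, the higher of the gene's own value and the lowest value among K-12 spots above background. On simulated data with the spreads of these 2280 genes, in which 200 genes were changed, the TiO2 against control comparison recovered 28.4% of genes changed by 0.5 on the log2 scale, 95.5% of those changed by 1 and 100% of those changed by 2. In that simulation 6.88% of the calls were false, and with nothing changed 0 genes were called. It drew noise independently for each gene, with the same spread in both groups. The real TiO2 arrays were less alike (pairwise correlations 0.9162 to 0.9421) than the control arrays (0.9585 to 0.9696). The simulated false share therefore need not hold for these data.

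For gene groups, 44 lists of K-12 genes were fixed before the data were examined. Each was tested with limma's camera at a preset correlation of 0.01, which compares a list with all other genes, and again with a correlation estimated from the data. limma's fry, which tests whether the members move on balance in 1 direction without comparing them with other genes, was an alternative. Adjusted p-values of lists are over the 44 lists. Genes were named by a rule fixed at the same time. It took the 8 largest increases and the 8 largest decreases among called genes whose 2 groups of arrays did not overlap, up to 4 called members of each list past the camera threshold by size of change, and up to 2 called members of each other list. Genes named outside this rule are marked as chosen after their values were seen. Array-level measures were compared by an exact two-sided permutation test, in which the smallest p that 4 against 4 arrays allow is 0.0286.

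The 75th percentile scaling of the original design, on normexp values, was kept as an alternative. The alternatives fixed beforehand covered scaling to the array median, the authors' value table and the criterion for dim probes (none, or all 8 arrays). They also covered testing all non-control probes, testing each probe on its own, replicate number or slide as a block, and array weights. An intensity trend with robust moderation, an unmoderated test per gene and stricter thresholds were among them too. So were leaving out each array in turn and the other list tests. Further ones were chosen after seeing the data: no background correction, correction from the negative control spots, spot means in place of medians, a signal-to-noise criterion, quantile normalization over K-12 probes alone, and scaling to the E1A control spots. Other-strain probes entered the normalization, the alternative that tested all non-control probes, and 1 of the array-level comparisons, the share of their spots above background. For probes outside the matched K-12 genes, a repeat of that alternative without TiO2 replicate 4 was also chosen after seeing the data. Arrays give no counts of molecules, so precision rests on the number of arrays and on signal over background.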

Results

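The study asked how the transcript levels of Escherichia coli respond to titanium dioxide (TiO2) nanoparticles. Cells of the laboratory strain K-12 MG1655 were kept for 5 h at 20 °C in the dark, shaken at 150 rpm in 10 mM NaCl, with 100 mg/l of the particles or with water in their place. Each of the 4 control and 4 TiO2 cultures was read on 1 array. Summed signal of K-12 genes above the negative control spots was 2984000 ± 307000 intensity units on control arrays and 1792000 ± 427500 on TiO2 arrays (SD, n = 4), and every TiO2 array lay below every control array. The difference had an exact permutation p of 0.0286, the smallest possible, and 0.143 after adjustment over 5 array-level comparisons. It was -1625000 on slide 1 and -757500 on slide 2. K-12 spots above background made up 52.9% to 66.0% on control arrays, 34.6% to 45.0% on TiO2 replicates 1 to 3 and 77.6% on TiO2 replicate 4. Probes for other E. coli strains were above background for 17.3% to 22.2% of spots on control arrays, 12.5% to 14.8% on TiO2 replicates 1 to 3 and 56.5% on TiO2 replicate 4.

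**Figure D1:**
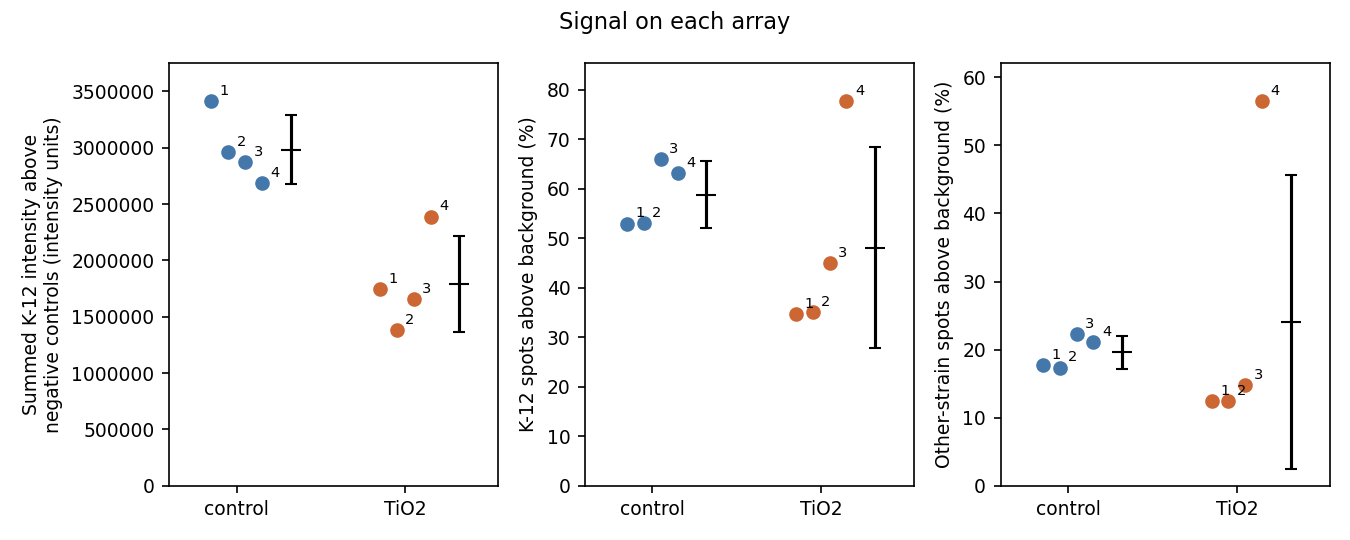
Signal per array, with control arrays in blue, TiO2 arrays in orange, replicate numbers beside the points and mean ± SD in black. The panels show summed K-12 intensity above the negative controls (intensity units), K-12 spots above background (%) and other-strain spots above background (%). Summed K-12 intensity was lower on all 4 TiO2 arrays, and TiO2 replicate 4 had 56.5% of its other-strain spots above background.

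Of the 8 genes with the largest increases with TiO2, osmB, ygaM, yjbJ, osmY and otsB belonged to the list of genes controlled by RpoS, while ydeI, glnK and ycfJ did not. The gene osmB (b1283), for an osmotically inducible lipoprotein, was 5.37-fold higher (log2 change 2.42 ± 0.26 SE, adjusted p = 0.000196). It was followed by ygaM (b2672, 5.08-fold), yjbJ (b4045, 4.34-fold), the periplasmic protein gene osmY (b4376, 4.24-fold), ydeI (b1536, 4.18-fold, with a log2 change of 2.06 that was 2.76 in the authors' value table) and otsB (b1897, 3.35-fold), which encodes the phosphatase of trehalose synthesis. The gene glnK (b0450), for a signalling protein of nitrogen status, was above background on all 4 TiO2 arrays and on 0 control arrays. Its bound of 3.12-fold higher equalled the measured fold and carries the same error (log2 change 1.64 ± 0.26 SE). The bound depended on the processing. The log2 change of glnK ran from 1.39 to 2.55 over the alternatives, the highest being in the authors' value table. The gene ycfJ (b1110) was 3.03-fold higher, and its call ended with scaling to the E1A control spots (log2 change 0.96, adjusted p = 0.13). The largest decreases were in ylaC (b0458, log2 change -1.74 ± 0.17 SE) and yebZ (b1840, -1.64 ± 0.18), which encode inner membrane proteins. Next came the 16S rRNA methyltransferase gene rsmG (b3740, -1.63 ± 0.15), the insertion-sequence gene insK (b3558, -1.51 ± 0.20), and dnaX (b0470, -1.29 ± 0.19), for subunits of DNA polymerase III. They were followed by the peroxidase gene ahpC (b0605, -1.28 ± 0.19), the regulator rspR (b1540, -1.27 ± 0.19) and the lipoprotein gene yafT (b0217, -1.27 ± 0.21). The value of insK is uncertain, since insertion sequences can occur in near-identical copies. By the naming rule, the 4 TiO2 arrays lay apart from the 4 control arrays in each of these 16 genes.

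**Figure D2:**
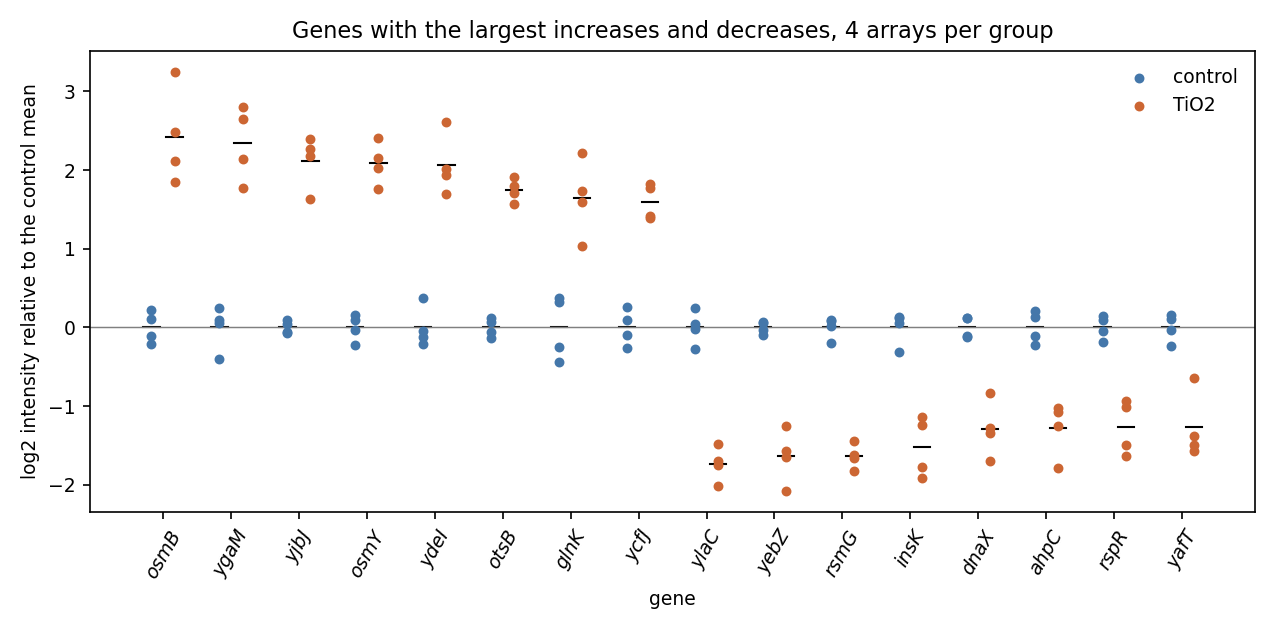
Normalized log2 intensity of the 8 genes with the largest increases and the 8 with the largest decreases, relative to each gene's control mean. Points are single arrays, control in blue and TiO2 in orange, and black bars are group means. The means of the TiO2 arrays ran from 2.42 for osmB to -1.74 for ylaC, and genes whose groups overlapped were not eligible.

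Across the genome, 333 of 2280 tested genes were called at an adjusted p under 0.05 in limma, 103 higher and 230 lower with TiO2. Of these, 69 changed by at least 1 on the log2 scale, 33 higher and 36 lower. The groups did not overlap in 494 genes, or 21.7% of those tested, where chance gives 2.86%. With slide as a block 395 genes were called, 121 higher and 274 lower. Within slide 1 alone 56 genes were called (18 higher, 38 lower) and within slide 2 alone 21 (14 higher, 7 lower). The position of the arrays on a slide went with the group and cannot be told apart from it. The called share that was lower was 69.1% and depended on the scaling. With the 75th percentile of each array, the main scaling of the original design, it was 54 higher and 591 lower. With the array median it was 46 and 723. With quantile normalization over K-12 probes alone it was 125 and 175, and with scaling to the E1A control spots 7 and 97. The median log2 change of all tested genes was -0.15 here. It was lower by 0.12 with the 75th percentile, by 0.19 with the array median and by 0.22 with E1A scaling, so the changes given are relative to each array's distribution. Of the 72 genes taken by the naming rule, 9 lost their call with the array median, 8 with the 75th percentile and 35 with E1A scaling. An unmoderated unequal-variance test per gene also cost 35 of them their call. Without TiO2 replicate 4, 405 genes were called (114 higher, 291 lower). Leaving out 1 control array lowered the count to 194 (replicate 1), 196 (replicate 2), 181 (replicate 3) and 155 (replicate 4). The fit takes the same spread for both groups, while the TiO2 arrays were less alike than the control arrays. These counts therefore need not mark any single array as unusual. Of the 72 named genes, 17, 15, 21 and 26 lost their call without control replicates 1 to 4, and 7, 10, 8 and 6 without TiO2 replicates 1 to 4.

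The list of genes controlled by RpoS, the sigma factor of stationary phase and general stress, was higher with TiO2. Of 27 measured members, 12 were called higher, 0 lower and 15 neither, and 18 were higher when adjusted over the list alone. Besides osmB, ygaM, yjbJ and osmY, it held otsB and dps (log2 change 1.22 ± 0.20 SE), which encodes a DNA-binding protein of starved cells. The median change was 0.56, and camera gave an adjusted p of 4.35e-15, but 0.15 with an estimated correlation. The median was 0.45 on slide 1 and 0.61 on slide 2, and 0.48 without TiO2 replicate 4. It was 0.26 with the array median, 0.33 with the 75th percentile, 0.23 with E1A scaling and 0.28 without a criterion for dim probes, with the camera call kept. With E1A scaling dps was not called (log2 change 0.67, adjusted p = 0.334).

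Genes of fatty acid oxidation were also higher, with 6 of 8 measured members called higher, 0 called lower and the same 6 when adjusted over the list alone. They included fadA (2.48-fold, log2 change 1.31 ± 0.17 SE) and fadB (2.28-fold), the subunits of the aerobic beta-oxidation complex. Also called were fadH (2.03-fold), for a reductase of unsaturated fatty acids, and fadI (1.78-fold), for a thiolase. The median change of the list was 0.74, with a camera adjusted p of 2.2e-07 and of 0.0692 with an estimated correlation. It was 0.85 on slide 1 and 0.67 on slide 2. With the array median it was 0.30, with the 75th percentile 0.38 and with E1A scaling 0.28, and the camera call was kept. The call of fadI ended under each of these (log2 change 0.39, 0.46 and 0.36, adjusted p = 0.114, 0.0597 and 0.641), and those of fadA, fadB and fadH ended with E1A scaling (adjusted p = 0.187, 0.345 and 0.398). Fatty acid and phospholipid synthesis had 4 of 20 members called lower and 0 higher, 5 lower when adjusted over the list alone. Among them were accA (-0.79 ± 0.18) for a subunit of acetyl-CoA carboxylase and fabH (-0.79 ± 0.17) for the enzyme that starts chain elongation.

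Sugar and glycerol uptake passed camera in the upward direction with an adjusted p of 0.00555, but not with an estimated correlation (adjusted p = 0.662). Only 3 of its 29 measured members were called, all higher, with the same number when adjusted over the list alone. These were manZ (1.62-fold) and manY (1.60-fold) of the mannose transporter and mtlA (1.59-fold) of the mannitol transporter. The median change was 0.15. With the 75th percentile scaling the median turned to -0.20, with the array median to -0.27 and with E1A scaling to -0.30, and the call was lost under each, as were those of manZ, manY and mtlA. The call also ended with only genes above background on all 8 arrays (adjusted p = 0.087), with a signal-to-noise criterion (0.0752) and in fry (0.0851). The median was 0.11 on slide 1 (adjusted p = 0.0706) and 0.23 on slide 2 (0.0096).

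Purine and pyrimidine synthesis was lower with TiO2, with 6 of 20 members called lower, 0 higher and 8 lower when adjusted over the list alone. The called members included the GMP synthesis genes guaB (-0.81 ± 0.17) and guaA (-0.72 ± 0.17), the purine gene purC (-0.76 ± 0.19) and ndk (-0.69 ± 0.19), for nucleoside diphosphate kinase. The genes purC and ndk were above background on 1 of 4 TiO2 arrays, and ndk lost its call under 10 of 24 alternatives. The median change was -0.45, and the camera adjusted p was 0.025, or 0.248 with an estimated correlation. The call also ended without TiO2 replicate 4 (adjusted p = 0.0637), in the authors' value table (0.0838), without background correction (0.0799), with negative-control correction (0.088), with the signal-to-noise criterion (0.0948) and with E1A scaling (0.0931). The adjusted p was 0.0948 on slide 1 and 0.0244 on slide 2, where the medians were -0.38 and -0.47.

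**Figure D3:**
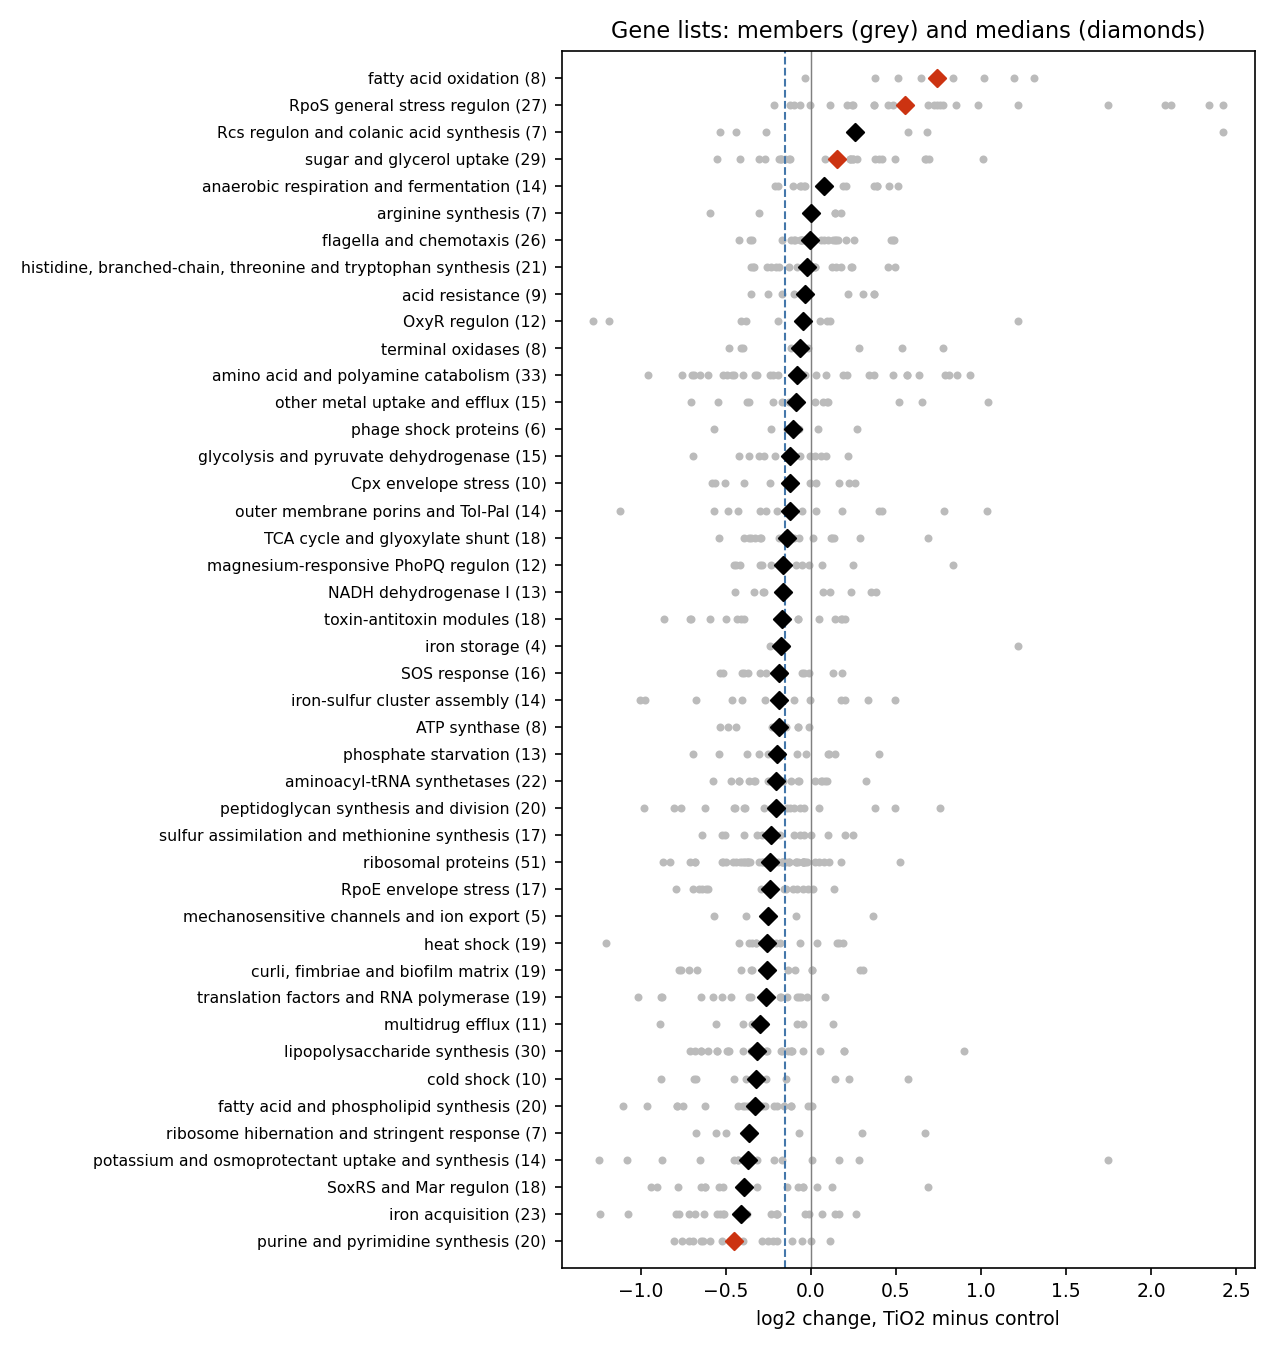
Log2 change (TiO2 minus control) of the measured members of the 44 gene lists (grey points) and the median of each list (diamonds, red where camera at the preset correlation gave an adjusted p under 0.05, which 0 of the 44 did with an estimated correlation). Numbers after the names are measured members and the dashed blue line is the median of all tested genes, -0.15. The medians of fatty acid oxidation, 0.74, and of the RpoS regulon, 0.56, lay highest, and that of purine and pyrimidine synthesis, -0.45, lay lowest.

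No other list passed camera, whose lowest adjusted p among them was 0.107, but many held called genes. Their counts are to be read against those of all 2280 tested genes, of which 103 were called higher and 230 lower. In the 24 alternatives that repeated camera at the preset correlation, 5 of these lists passed as lower under some. They were fatty acid and phospholipid synthesis (7 of 24), ribosomal proteins (7), translation factors and RNA polymerase (5), iron acquisition (4) and RpoE envelope stress (3). The Rcs list passed as higher in 2. With the array median, the 75th percentile and E1A scaling, the first 3 of these and the RpoE list all passed as lower. With the 75th percentile, the main scaling of the original design, camera gave ribosomal proteins an adjusted p of 1.9e-10 and translation factors and RNA polymerase 0.000129. Under that scaling the RpoS list was at 1.54e-11 and fatty acid oxidation at 5.01e-06. The median of the ribosomal list, -0.24 in the main setting, ran from -0.84 to -0.16 over 25 alternatives. Among osmoprotectant and potassium genes, the changes went both ways. The trehalose gene otsB was higher, while 4 of the 14 measured members were lower (5 when adjusted over the list alone), including the proline and betaine transporter gene proP (-1.25 ± 0.15). In the outer membrane, the porin gene ompF was 2.05-fold higher and tolR, of the Tol-Pal complex, was lower (-1.12 ± 0.18). The call of ompF ended with the array median (log2 change 0.34, adjusted p = 0.209), the 75th percentile (0.41, adjusted p = 0.12) and E1A scaling (0.31, adjusted p = 0.693). These genes lay among 2 higher and 1 lower of 14 porin and Tol-Pal genes, the same when adjusted over the list alone. The RpoE envelope stress list had 3 of 17 members lower (6 over the list alone). Among them were rseC (-0.79 ± 0.21, call lost under 7 of 25 alternatives) and bamA (-0.66 ± 0.15), the latter for outer membrane protein assembly. The Cpx list had 1 of 10 lower, yebE (-0.58 ± 0.16, call lost under 10 of 25 alternatives), and 3 when adjusted over the list alone. Of 7 measured genes of the Rcs system and colanic acid synthesis 3 were higher, both overall and adjusted over the list alone, which also called 1 lower. They included osmB and the regulator gene rcsB (1.61-fold), whose call ended with the array median (log2 change 0.19), the 75th percentile (0.27) and E1A scaling (0.17). Lipopolysaccharide synthesis had 1 of 30 genes higher and 4 lower (7 lower over the list alone). In it lpxC, for the committed step of lipid A synthesis, was 1.87-fold higher and waaB was lower (-0.71 ± 0.17). The call of lpxC ended under the same 3 scalings, with log2 changes of 0.38, 0.46 and 0.35. Cell wall synthesis and division had 1 of 20 higher and 4 lower, the same when adjusted over the list alone. Lower members included mrdA (-0.98 ± 0.25) and dacA (-0.80 ± 0.21), for penicillin-binding proteins. The gene mrdA was above background on 2 of 4 TiO2 arrays and lost its call under 5 of 23 alternatives, and dacA lost its call under 6 of 25.

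In the OxyR list dps was 2.33-fold higher and ahpC lower, among 1 higher and 2 lower of 12, the same when adjusted over the list alone. In the SoxRS and Mar list 1 of 18 members was higher and 5 lower (1 and 9 over the list alone), the latter including the regulator genes soxS (-0.91 ± 0.17) and marR (-0.94 ± 0.29). The call of soxS was kept under all 25 alternatives, while that of marR was lost under 15 of 23. Among these were slide as a block (adjusted p = 0.0571) and spot means (0.0998). The gene marR was above background on 2 of 4 TiO2 arrays. The higher member was fumC (1.61-fold), for a fumarase, whose call ended with the array median (log2 change 0.40, adjusted p = 0.0611) and E1A scaling (0.37, adjusted p = 0.633). The median of this list was -0.40, and fry called it lower (adjusted p = 0.00282) while camera did not (adjusted p = 0.149). Iron acquisition had 3 of 23 genes lower and 0 higher (9 lower over the list alone), among them fhuF (-1.07 ± 0.16) for a siderophore-iron reductase and fepA (-0.80 ± 0.22) for the enterobactin receptor. In the authors' value table fhuF was at -1.67, and fepA lost its call under 7 of 25 alternatives. In iron-sulfur cluster assembly, iscX (-1.01 ± 0.21) and hscB (-0.98 ± 0.16) lay among 3 of 14 lower, with 1 higher, the same when adjusted over the list alone. Among 15 genes for other metals 2 were higher and 1 lower (3 and 2 over the list alone), including the copper chaperone gene cusF (2.06-fold) and the magnesium transporter gene corA (-0.71 ± 0.20). The call of corA was lost under 11 of 24 alternatives, and that of cusF with E1A scaling (log2 change 0.83, adjusted p = 0.208). Of 4 iron storage genes only dps was called, by either adjustment, and of 12 genes of the magnesium-responsive PhoPQ list only treR (1.79-fold higher), by either adjustment, which encodes the repressor of trehalose use. With E1A scaling treR was not called (log2 change 0.50, adjusted p = 0.49).

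Genes of protein synthesis that were called were lower. They were 5 of 51 ribosomal protein genes (5 over the list alone), including rpsO (-0.87 ± 0.21) and rpsU (-0.83 ± 0.15). That share was close to the share of all tested genes called lower, 230 of 2280, and by itself does not set ribosomal proteins apart. Of 19 translation factor and RNA polymerase genes 5 were lower (7 over the list alone), including the transcription factor genes nusA (-0.88 ± 0.18) and nusG (-0.88 ± 0.22). Of 22 aminoacyl-tRNA synthetase genes 1 was lower, lysS (-0.58 ± 0.17, call lost under 13 of 25 alternatives), and 0 when adjusted over the list alone. Of 19 heat shock genes 1 was lower, the chaperonin gene groS (-1.21 ± 0.17), with the same count over the list alone. Cold shock had 2 of 10 lower, cspA (-0.69 ± 0.17) and raiA, again 2 over the list alone. The gene raiA, for a ribosome hibernation factor, was saturated on all 4 control arrays and was at least 1.60-fold lower with TiO2 under the normalization used here (adjusted p = 0.0292). That bound depended on the scaling. The log2 change of raiA between the measured levels, -0.67 here, was -1.35 with the array median, -1.28 with the 75th percentile, -1.38 with E1A scaling and -0.28 in the authors' value table (adjusted p = 0.151), and the call was lost under 8 of 25 alternatives. It was also the called member of the hibernation and stringent response list, where 1 of 7 was lower, against 1 higher and 3 lower over the list alone.

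In central metabolism, cydB of a terminal oxidase was 1.71-fold higher, the called member of 8 terminal oxidase genes (2 higher and 2 lower over the list alone). Its call ended with the array median (log2 change 0.34, adjusted p = 0.254), the 75th percentile (0.41, adjusted p = 0.152) and E1A scaling (0.31, adjusted p = 0.693). Of 18 genes of the TCA cycle and glyoxylate shunt fumC was higher and sdhA lower (-0.54 ± 0.16, call lost under 12 of 25 alternatives), with fumC alone when adjusted over the list alone. Of 15 glycolysis genes pgk was lower (-0.69 ± 0.20, call lost under 11 of 25 alternatives and a log2 change of -1.30 with E1A scaling), and 0 when adjusted over the list alone. The list named amino acid and polyamine catabolism, which also holds genes of polyamine synthesis and of uptake, had 6 of 33 members higher and 5 lower. Over the list alone these counts were 6 and 7. Among them were the threonine and serine transporter gene tdcC (1.91-fold higher) and the spermidine synthase gene speE (-0.96 ± 0.16). With E1A scaling tdcC was not called (log2 change 0.62, adjusted p = 0.384). In sulfur assimilation and methionine synthesis 1 of 17 was lower, cysJ (-0.64 ± 0.18, call lost under 9 of 25 alternatives), and 0 over the list alone.

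Curli, fimbriae and biofilm matrix had 4 of 19 lower (4 over the list alone), with fimI (-0.78 ± 0.20, call lost under 6 of 25 alternatives) and bhsA (-0.77 ± 0.17). Toxin-antitoxin modules had 3 of 18 lower (4 over the list alone), with the antitoxin genes yefM (-0.86 ± 0.17) and chpS (-0.59 ± 0.15). Of 11 multidrug efflux genes 2 were lower by either adjustment, emrA (-0.89 ± 0.22) and emrB (-0.56 ± 0.15), both above background on 1 of 4 TiO2 arrays. Of 16 SOS genes 1 was lower, the division inhibitor gene sulA (-0.53 ± 0.16), and 0 over the list alone. The call of sulA was lost under 15 of 25 alternatives, with spot means (adjusted p = 0.0715) and E1A scaling (0.0866) among them. No member was called, by either adjustment, among 26 flagella and chemotaxis, 21 histidine, branched-chain, threonine and tryptophan synthesis, 14 anaerobic respiration and fermentation, 13 NADH dehydrogenase I, 13 phosphate starvation and 9 acid resistance genes. The same held for 8 ATP synthase, 7 arginine synthesis, 6 phage shock and 5 mechanosensitive channel and ion export genes. With an estimated correlation 0 of the 44 lists passed camera (4 had an unadjusted p under 0.05), while fry called 17, of which 3 were higher and 14 lower. Since fry does not compare a list with other genes, a lower call need not set a list apart. The median log2 change of all tested genes was itself -0.15. The aminoacyl-tRNA synthetase list, for example, had a median of -0.20 and was called by fry (adjusted p = 0.00658).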

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

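The tests on local background, on the E1A spots, with an array left out and of the splits of the arrays were written down after their values had been seen, and the others before. TiO2 replicate 4 stood apart from the other 3 TiO2 arrays in the share of other-strain spots above background, 56.5% against 12.5% to 14.8%, and also lay above the 17.3% to 22.2% of the control arrays, in probes outside the genes compared in the report. Its local background was 89 intensity units, the lowest of the 8 arrays (99 to 118 on the others), which argues against a raised background between the spots. E. coli DNA left in the labelled sample would brighten dim K-12 probes more than probes for other strains. The ratio of their medians above the negative controls was 1.07 (95% bootstrap interval over probes 1.0 to 1.17), which argues against it as the whole cause. On the spots themselves signal without E. coli target was raised, to 159 on dark spots (105 to 127 on the other arrays), 151 on negative controls (114 to 136) and 237 on eQC spots (126 to 156), so nonspecific binding of labelled material is a candidate explanation that was not tested on its own, and a biological one was not tested.

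Summed K-12 signal was lower on the TiO2 arrays, with a mean 0.601 times that of the controls. Against a loss from a few very bright genes, the ratio without the 20 brightest genes was 0.615, and every TiO2 array still lay below every control array (1780000 or less against 1847000 or more). Weaker hybridisation, washing or scanning should lower the E1A control spots as well. These differed by -0.07 on the log2 scale, and the log2 ratio of K-12 to E1A signal by -0.69, with an exact permutation p of 0.171 and overlapping groups (9.51 to 10.7 against 10.4 to 11.4). The spread of the E1A spots keeps this open, and it cannot be told apart from a lower K-12 signal with TiO2.

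The higher RpoS list, whose call was lost with an estimated correlation (adjusted p = 0.15), was weighed against a trend with brightness and against 1 unusual TiO2 array. Its median lay above 100% of 10000 random lists matched on control brightness, whose highest median was 0.21, which argues against a trend with brightness, though genes were drawn singly and such lists do not carry the correlation between members. With each TiO2 array left out in turn the list median stayed at least 0.65 above that of all genes, which argues against a single array. The median itself ran from 0.23 to 0.75 over the 8 scalings run, so that its direction did not turn and its size depended on the scaling. Position on the slide goes with the group and stays open, and a response of the cells to TiO2 is a hypothesis that these tests do not establish.

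Of 144 groups of 4 arrays in the 72 genes the naming rule took, 6 held an array far from the other 3, all among controls, where chance gives about 7.2. Control replicate 1 was at a log2 level of 9.09 for insK (others 9.46 to 9.54), 8.44 for fumC (others 8.29 to 8.31) and 8.47 for fadA (others 8.95 to 9.01). Control replicate 2 was at 8.3 for fadH (others 8.67 to 8.74), control replicate 3 at 11.86 for groS (others 11.49 to 11.5) and control replicate 4 at 11.14 for rpsO (others 11.38 to 11.42).

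Among the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, gave 333 called genes, and the highest other gave 1. The same held for the 103 higher and 230 lower genes, where 1 split, the real one, reached each count and the highest others gave 0 and 1. The 3 counts thus stood far above those of any other split. Every other split, however, mixes control and TiO2 arrays within its groups. A difference between control and TiO2 then adds to the spread within them and lowers the count, so the size of this contrast is not evidence of its own. But 1 of 35 is the smallest share that these splits allow, and the test was written down after the counts had been seen. It therefore does not exclude chance. Of the 35 splits, 18 put 2 arrays of each slide in both groups, too few for a share under 0.05 (the smallest is 5.56%). Among these 18 the real split gave 333 genes and the highest other 1. As many as 4 lists past camera came from 6 of the 35 splits, with 7 in the highest other, so chance cannot be excluded for the number of lists.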

How the results depend on the processing

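Tests without background correction, with negative-control correction, with spot means, with the signal-to-noise criterion, with quantile normalization over K-12 probes and with E1A scaling were chosen after seeing the data. The quantile normalization of the main setting was chosen after the files were seen, in place of the 75th percentile fixed in the design. Of 72 genes taken by the naming rule, 0 turned direction under any of the 25 alternatives that gave a gene value. Of these genes, 23 kept their call under all alternatives that could test them. Most of the alternatives could not turn a direction. The groups overlapped in none of these genes, so leaving out or weighting arrays could not. Blocks, other tests and other probe criteria kept the same changes. Only the 8 alternatives with another scaling, background correction, spot summary or value table could turn a direction. Against 333 called genes (103 higher, 230 lower) and 4 lists, the array median gave 769 (46, 723) and 7 lists, the 75th percentile 645 (54, 591) and 7, and E1A scaling 104 (7, 97) and 7. The authors' value table gave 624 (170, 454), no background correction 608 (175, 433) and negative-control correction 637 (176, 461). Without a criterion for dim probes 196 genes (121 lower) and 8 lists passed, and with all non-control probes tested 8 lists. The signal-to-noise criterion gave 2 lists. An unmoderated unequal-variance test per gene gave 133 (59, 74), an adjusted p under 0.01 gave 108 (49, 59) and a log2 change of at least 1 gave 69 (33, 36), the last by their stricter construction. For the others the cause was not tested. Among lists, an estimated correlation left 0 and fry gave 17. The median of sugar and glycerol uptake turned to -0.27 with the array median, -0.20 with the 75th percentile and -0.30 with E1A scaling, against 0.15. Under the alternatives run, fry included, the adjusted p of the RpoS list ran up to 0.15 and that of fatty acid oxidation up to 0.0692, both with an estimated correlation, and each passed under the other 25. That of purine and pyrimidine synthesis ran from 0.00136 to 0.248 and was lost under 7 of 26. Leaving out 1 array gave 155 to 405 called genes, 64 to 114 higher, 91 to 291 lower and 3 to 5 lists, on fewer samples. With replicate number as a block 345 genes were called (103 higher, 242 lower). Same-numbered arrays deviated together with correlations of 0.18, 0.12, 0.17 and -0.013, and not every array correlated best with its own number, so the numbers were not taken as pairs. Quantile normalization of the processed signal was not run, as the files hold no such column. Signal over background limits the results, since 1772 K-12 genes were too dim to test.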

Other observations

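The genes named in this part were chosen after their values were seen, and the tests of the regulons were chosen then too, before the members that had not been called were examined. The repeat without TiO2 replicate 4 was also chosen after seeing the data. The oligopeptide transporter operon was lower with TiO2, with oppA (-1.26 ± 0.18 SE), oppB (-1.16 ± 0.20), oppC (-1.11 ± 0.16) and oppF (-0.80 ± 0.18) called and oppD at -0.37 (adjusted p = 0.321 in limma). The dipeptide-binding protein gene dppA was higher (1.07 ± 0.18), as was livK (0.98 ± 0.17) for a leucine-binding protein, the called 1 of 3 measured leucine transport genes. The others were livH at 0.29 and livJ at 0.12 (adjusted p = 0.342 and 0.70 in limma), of which livJ turned sign under 1 alternative. The neighbouring genes yqjC (1.22), yqjD (0.88), yqjE (1.19) and yqjK (0.94) were all called higher. So were rpoS itself (0.76 ± 0.17), the adjacent nlpD (0.72 ± 0.17) and the regulator gene arcA (0.81 ± 0.19). Of 6 measured glycogen genes 2 were called, glgC (1.02 ± 0.14) and glgS (0.88 ± 0.22), both higher. The others were glgP at 0.45, glgA at 0.31, glgX at 0.15 and glgB at -0.04, of which glgB, glgP and glgX turned sign under some alternatives. None of the called genes turned direction under the alternatives that gave it a value, most of which did not rescale the arrays, but calls were lost. They were kept under 21 of 25 alternatives for rpoS (lowest change 0.23), 19 of 25 for nlpD (lowest 0.08), 20 of 25 for arcA (lowest 0.31) and 18 of 25 for glgS (lowest 0.41). For each of the other called genes of this paragraph they were kept under all or all but at most 3.

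Of 14 measured DNA replication genes, looked up for this purpose, 5 were called lower and 0 higher. Beside dnaX these were holB (-0.93 ± 0.15), dnaB (-0.77 ± 0.20), dnaT (-0.70 ± 0.18) and dnaG (-0.67 ± 0.17), while dnaA was at -0.16 (adjusted p = 0.536 in limma). The call of dnaB was kept under only 11 of 23 alternatives, with changes from -0.94 to -0.25, that of dnaT under 18 of 24 and that of dnaG under 21 of 25. The adjacent IS150 genes insJ (-1.20 ± 0.14) and insK were both lower. So were ygeK (-0.95 ± 0.21), ygeN (-1.09 ± 0.16), ygeO (-1.08 ± 0.16) and ygeQ (-1.17 ± 0.18), from 1 region of the chromosome. Of 4 osmoprotectant transporter genes looked up beside proP, 3 were lower and proX was at -0.43 (adjusted p = 0.077 in limma). The 3 were proV (-0.88 ± 0.17), proW (-0.65 ± 0.16) and betT (-1.08 ± 0.31), but betT kept its call under 15 of 24 alternatives and proW under 18 of 24. Of 8 measured antioxidant genes, looked up likewise, 1 was called higher and 2 lower. Here grxA (-1.19 ± 0.24) and sodA (-0.65 ± 0.14) were lower and sodC (0.69 ± 0.20) was higher, the last with its call kept under 13 of 24 alternatives, while katG was at 0.11 (adjusted p = 0.663 in limma), sodB at 0.10, oxyR at -0.02, gor at -0.04 and trxC at -0.41 (adjusted p = 0.222 in limma). Of these katG, sodB, oxyR and gor turned sign under some alternatives.

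A hypothesis is that the rise of glnK was part of a wider rise of the nitrogen limitation regulon controlled by NtrC. Of 27 measured members of a list of 55 genes, 10 were called higher and 0 lower, including glnH (1.49 ± 0.17), glnA (1.13 ± 0.14), argT (0.98 ± 0.22) and potF (0.86 ± 0.15). Among the 10 were also glnK, which prompted the hypothesis, and yeaH (0.85), which like the uncalled yeaG belongs to the RpoS list too. The test used the 17 members not called. Their median, 0.10, lay above 99.5% of random lists of uncalled genes matched on brightness. All uncalled genes had a median of -0.12, and 13 of the 17 lay above that median. The test was run in the main setting alone. There the median of all 27 measured members was 0.42, and over 25 alternatives it ran from 0.04 to 0.50. A wider rise would give such a lean, but the members differed. The genes glnL (0.17), nac (0.10, adjusted p = 0.76 in limma) and cbl (0.08) changed little. Lower, without being called, were codA (-0.40), codB (-0.32), gltK (-0.20), rutB (-0.13), yhdZ (-0.11), gltL (-0.05) and yeaG (-0.004). The result may also reflect operon structure, since uncalled members share operons with called ones.

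A second hypothesis is that osmB, ydeI and ycfJ rose with other genes activated by the Rcs envelope stress system. Of 17 measured members of a list of 39 genes, 8 were called higher and 1 lower, ymgD (-0.53 ± 0.15). The 8 included osmB, ydeI and ycfJ, which prompted the hypothesis, as well as loiP (1.11 ± 0.27) and ftsZ (0.76 ± 0.16). The 8 uncalled members had a median of 0.25, above 99.7% of matched random lists. This test too was run in the main setting alone. There the median of all 17 measured members was 0.57, and over 25 alternatives it ran from 0.16 to 0.71. Of the 8, 5 lay above the median of uncalled genes, close to an even split, and rcsA (-0.44) and ymgG (-0.54) were among the others. Genes of the random lists were drawn singly, so such lists do not carry the correlation between members. The result may also reflect operon structure, where uncalled members share operons with called ones. A wider rise thus stays a hypothesis that this test does not establish. The genes osmB and osmC also belong to the RpoS list, so the regulators may not be separable from these data.

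On the arrays, 1242 probes outside the matched K-12 genes passed the background criterion when all non-control probes were tested together, and 109 of them were called by limma, 43 higher and 66 lower. TiO2 replicate 4 stood apart in such probes, with 56.5% of other-strain spots above background against 12.5% to 14.8% on the other TiO2 arrays. Without that array 117 of the same 1242 were called, 51 higher and 66 lower. The log2 changes of the 2 slides correlated across K-12 genes (Pearson 0.597, Spearman 0.518, genes not being independent replicates). In limma's test of the interaction of group and slide 0 genes passed, and 142 had an unadjusted p under 0.05. With 2 arrays per group on a slide this does not show equal changes, and dps, for example, was at 0.79 on slide 1 and 1.66 on slide 2.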
